A study of Phaseolus coccineus with 4 samples.

How the data were processed

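RNA was sequenced from 4 laser-captured samples of scarlet runner bean (cultivar Hammond's Dwarf Red Flower), 2 of the embryo proper and 2 of the suspensor. Per the labels' protocols, plants were kept at 22 degrees with 16 hours of light, and seeds of 1.6 to 2.5 mm were fixed in ethanol and acetic acid at 6 days after hand pollination. The regions were then captured from paraffin sections of 6 microns. The protocols state that 5 ng of total RNA per sample was turned into cDNA and amplified with the Ovation RNA-Seq kit, and that about 500 ng of the product entered Illumina library preparation with 10 cycles of PCR. Low input and this amplification add variation between libraries, and reads are not independent molecules because no molecular identifiers are described. Each sample's region and replicate number come from its title, which calls the replicates biological. No label says whether samples with the same number came from the same embryos, plants or day.

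The authors deposited 1 table of RPKM per library. The submitters' processing notes name Bowtie 0.12.7 and bedtools. The genome build, the gene annotation, the treatment of reads that match several genes and of strand, and the set of reads that the depth was taken over are not given in the sources used here. Genes that share reads with near-identical copies or overlapping genes could therefore carry each other's signal. The files hold only values above 0, and a gene missing from a file was set to 0. None of the 19883 gene IDs matched the 34063 genes of the reference table of a Phaseolus coccineus assembly. This does not show that the IDs have no names in another annotation. No ID was paired with a name here. For that reason the 27 gene lists prepared before the data were examined were not tested, and neither camera nor fry was run. No coordinates are given.

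RPKM values are not counts, so the main test was made on a log scale. Values were taken as log2(RPKM + 1), genes with an RPKM of at least 1 in at least 2 of the 4 libraries were kept (13527 genes), and limma 3.58.1 in R 4.3.3 was fitted with region as the only term and eBayes with a trend. All adjusted p-values are from limma, two-sided, with the Benjamini-Hochberg method and a threshold of 0.05. With 2 libraries per region, the test relies on the spread that limma shares across genes (prior degrees of freedom 4.33). The 2 genes with the largest rise and the 2 with the largest fall are named, among called genes whose libraries did not overlap between regions and whose mean was at least 10 RPKM in the higher region. This rule, the thresholds, the test and the alternatives were set before the data were examined, unless stated otherwise. Data were simulated with the means of this comparison and the spread that limma fitted to it. In them, 200 of 13527 genes were changed, all drawn from genes above a set mean level. The fit called 12% of genes changed by 2 on the log2 scale and 97% of those changed by 6, and 8.40% of its calls were false. The shares called were not measured for changed genes of lower level. Smaller differences than those called can thus be missed at this size.

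The depth was recovered from the values. An RPKM is a whole number of reads divided by gene length and depth, so genes with equal low read numbers give the ratio of depths, and the depth is the value for which lengths are whole numbers of bases. With it, 100% of the 13527 tested genes had whole reads in every library at a common length between 50 and 20000 bases (tolerance 0.02 reads). The recovered reads summed to 97.3%, 97.4%, 98.4% and 98.7% of the recovered depths. In simulated tables, the reads of 95.0% of genes were recovered exactly, and those of 98.8% exactly or up to a common divisor. At the median length of 1628 bases, 1 read was worth 0.0158, 0.0187, 0.0108 and 0.0130 RPKM in embryo proper replicates 1 and 2 and suspensor replicates 1 and 2. Such floors cover counting error only.

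The replicate numbers are shared by the regions, but no label says that they pair the samples, so the main fit was planned without a block. As a check, the deviations of same-numbered libraries from their region means did not correlate (Pearson's r = -0.03 across the tested genes, Spearman's rho = -0.02). The alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 RPKM, 3 other scalings, eBayes without a trend and with robust estimation, an adjusted p under 0.01, a minimum fold change of 2, the replicate block and leaving out each library. After the data were examined, 4 more were added, voom from limma on the recovered reads, the depth counted without the reads of the 10 highest genes of any library, and a subtraction of the signal shared with the other region at 2 percentiles, the 5th first and then the 1st, which is the one reported because the 5th took over 5% from the suspensor libraries. Permutation and bootstrap tests used Python 3.11.15 and numpy 2.4.6.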

Results

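Transcript levels were measured by RNA sequencing in 2 regions of the globular-stage embryo of scarlet runner bean (Phaseolus coccineus). The embryo proper is the part of a young embryo that forms the plant body, and the suspensor is the terminally differentiated stalk that joins it to the surrounding seed tissue and feeds it. Both regions were cut by laser from paraffin sections of seeds collected 6 days after pollination. The data comprise 4 libraries, 2 biological replicates per region. The depth recovered from the deposited values was 38967825 and 32855045 reads in embryo proper replicates 1 and 2, and 56899297 and 47091897 reads in suspensor replicates 1 and 2. The deposited tables list a gene only where its RPKM (reads per kilobase of gene length, scaled to the library's depth) is above 0, and together they list 19883 genes, of which 14588 are in all 4 libraries. The tables identify genes by IDs alone and pair none of them with a name, so genes are described here by level, rank and direction of difference, and no pathway or marker list was examined.

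The libraries were first compared with each other to set the spread between replicates beside the difference between regions. Across genes, Pearson's r of log2(RPKM + 1) was 0.870 between the embryo proper replicates and 0.830 between the suspensor replicates. The 4 pairs made of a library from each region gave r from 0.688 to 0.739. Spearman's rho was 0.847 and 0.819 within the regions and from 0.672 to 0.720 between them. Of the 100 genes with the highest RPKM in a library, 83 were shared by the embryo proper replicates and 82 by the suspensor replicates, but only 37 to 48 by libraries of different regions. The SD of the log2 difference across genes was 1.18 between embryo proper replicates and 1.35 between suspensor replicates. Over genes of all levels together, a 2-fold difference thus lay within the usual difference between replicates. This does not hold for each gene, as some abundant genes varied less. These values describe the libraries, since genes are not independent replicates.

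The suspensor drew far more of its transcript signal from a few genes than the embryo proper did. The 10 most abundant genes held 37.8% ± 9.67 of the summed RPKM in the suspensor (SD, n = 2) and 11.3% ± 1.32 in the embryo proper (SD, n = 2). A single gene reached 124904 RPKM in suspensor replicate 1 and 239138 RPKM in suspensor replicate 2, which was 16.1% and 28.5% of the summed RPKM of those libraries. The same gene stood at 2442 ± 519 RPKM in the embryo proper (SD, n = 2), and its log2 fold change, suspensor over embryo proper, was 6.16 with a standard error of 0.333 (limma, adjusted p = 0.00207). The most abundant gene in either embryo proper library held no more than 2.96% of the summed RPKM. That gene, Phvul.011G045000, named here after its values were seen, was also the fourth most abundant in the suspensor. It stood at 17951 ± 3972 RPKM in the embryo proper and 20998 ± 8234 RPKM in the suspensor (SD, n = 2), and the difference did not pass the test (log2 fold change 0.19, standard error 0.31, limma adjusted p = 0.756). A share of 50% of the summed RPKM was reached with 262 and 280 genes in the embryo proper replicates, and with 106 and 27 genes in the suspensor replicates. With 2 libraries per region, no exact test of these shares can go below a two-sided p of 0.333.

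**Figure D1:**
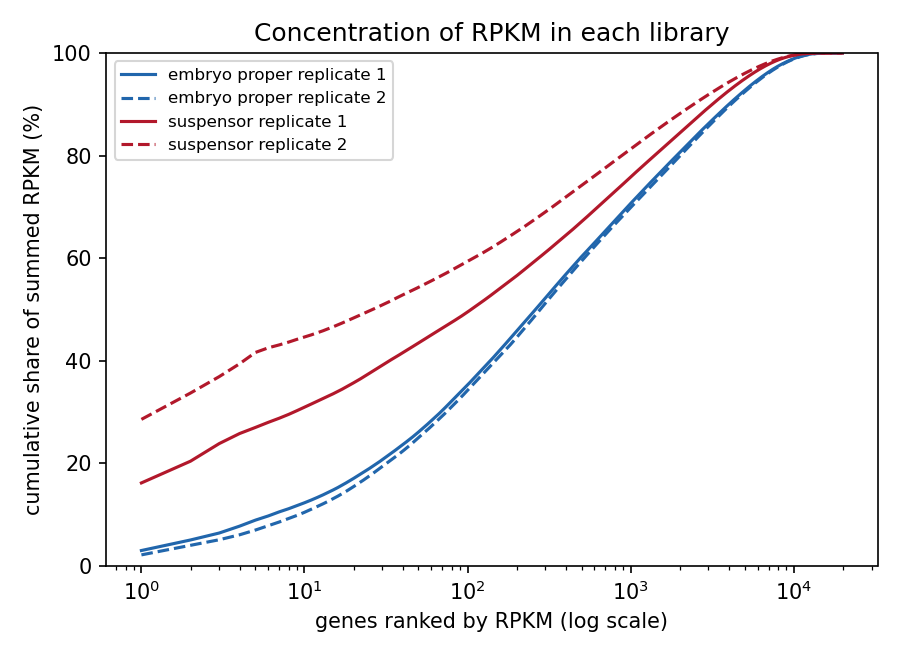
Cumulative share of the summed RPKM (vertical axis, percent) against genes ranked by RPKM from the highest down (horizontal axis, log scale), with 1 line per library. The 10 highest genes held 30.9% and 44.6% in suspensor replicates 1 and 2, against 12.3% and 10.4% in embryo proper replicates 1 and 2.

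More genes were detected in the embryo proper than in the suspensor. Genes with an RPKM of at least 1 numbered 13018 ± 131 in the embryo proper and 11412 ± 41.7 in the suspensor (SD, n = 2). The suspensor libraries were the deeper ones, but RPKM is scaled to depth. A limit in RPKM also depends on the share of reads that the most abundant genes take. The counts in this paragraph were not repeated with another scaling. By a fixed rule of size, 668 genes had an RPKM of at least 1 in both embryo proper libraries and under 0.1 in both suspensor libraries, and 100 genes met the reverse rule. At the median recovered gene length of 1628 bases, 3 reads correspond to 0.0324 to 0.0561 RPKM, so the limit of 0.1 lay above that floor in each library. The excess of genes found in the embryo proper alone was seen also with limits of 5 and 0.5 RPKM, which gave 426 and 105 genes. The counts were closer in ratio when an estimate of the signal shared with the other region was subtracted, an alternative added after the data were examined, which gave 787 and 224 genes, or 3.51 in the embryo proper for each in the suspensor against 6.68 before. Asking this of fewer libraries raised both counts, to 1197 and 195 without embryo proper replicate 1, 1112 and 203 without embryo proper replicate 2, 957 and 328 without suspensor replicate 1, and 1174 and 416 without suspensor replicate 2.

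The main comparison asked which genes differ in level between the suspensor and the embryo proper. Of 13527 genes with an RPKM of at least 1 in at least 2 libraries, 284 were higher and 638 were lower in the suspensor (limma on log2(RPKM + 1), Benjamini-Hochberg adjusted p under 0.05). Before adjustment, 3816 genes had a p under 0.05, of which 1107 were higher in the suspensor. The called differences were large. The median log2 fold change was 4.29 among the genes called higher, and their largest was 6.63. Among the genes called lower, the median size of the log2 fold change was 3.89 and the largest was 7.90. At least an 8-fold difference was found for 236 of the higher and 448 of the lower genes, and at least a 32-fold difference for 71 and 131. Fold changes are on the log2(RPKM + 1) scale, which understates the change of genes with low values. In all 922 called genes, the libraries of the regions did not overlap, as was the case for 7520 (55.6%) of all tested genes, against 33.3% by chance for 2 libraries against 2. With 2 libraries per region, the number of calls fell when any library was left out. Such a fit has 1 residual degree of freedom fewer, so the fall does not show that the calls rest on a given library. Without embryo proper replicate 1 or without embryo proper replicate 2, limma called 0 genes, with 648 and 632 higher and 2043 and 1885 lower at an unadjusted p under 0.05. Without suspensor replicate 1 it called 20 genes higher and 27 lower, and without suspensor replicate 2 it called 21 higher and 26 lower.

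The genes called higher in the suspensor were mostly abundant there. Their median RPKM in the suspensor was 116, with 155 genes at 100 or more and 33 at 1000 or more. The genes called lower had a median RPKM of 56.0 in the embryo proper, with 239 genes at 100 or more and 73 at 1000 or more. Over all tested genes, the median log2(RPKM + 1) was 3.17 and 2.95 in suspensor replicates 1 and 2. It was 3.43 and 3.49 in embryo proper replicates 1 and 2. The test found mainly large differences, which favours genes that are high in 1 region, so these levels partly reflect the test. Of the 100 most abundant genes of the suspensor, 42 were called higher there, 16 were called lower and 42 passed neither way. Of the 100 most abundant genes of the embryo proper, 69 were called lower in the suspensor, 2 were called higher and 29 were not called. The 2 sets of 100 had 40 genes in common.

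**Figure D2:**
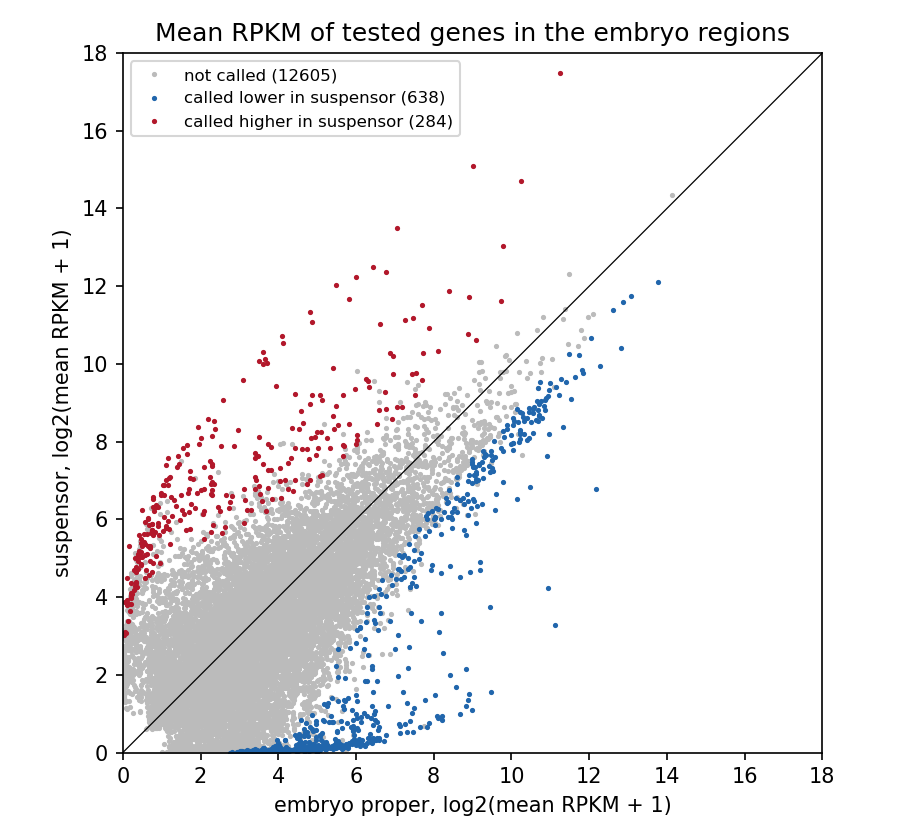
Mean RPKM in the suspensor (vertical axis) against the embryo proper (horizontal axis), both as log2(mean RPKM + 1), for the 13527 tested genes, with 284 genes called higher and 638 called lower in the suspensor in colour and the line of equal values drawn. The gene highest in the suspensor lies far above the others at a mean of 182021 RPKM.

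By the rule fixed beforehand, the gene with the largest rise on the log2(RPKM + 1) scale was Phvul.006G125400, with 16.0 ± 0.255 RPKM in the embryo proper and 1691 ± 14.2 RPKM in the suspensor (SD, n = 2). Its log2 fold change was 6.63 with a standard error of 0.34 and a 95% interval of 5.81 to 7.46 (limma, adjusted p = 0.00207). The second, Phvul.001G029200, was nearly equal, and with a pseudocount of 0.1 its rise was the larger of the 2. It stood at 11.3 ± 0.0708 RPKM in the embryo proper and 1267 ± 518 RPKM in the suspensor (SD, n = 2), a log2 fold change of 6.63 with a standard error of 0.44 (adjusted p = 0.00279). The largest fall on that scale was that of Phvul.004G006200, from 509 ± 22.4 RPKM in the embryo proper to 1.13 ± 0.137 RPKM in the suspensor (SD, n = 2). Its log2 fold change was -7.90 with a standard error of 0.52 and a 95% interval of -9.16 to -6.65 (adjusted p = 0.00279). Phvul.009G118900, whose fall was the larger of the 2 with a pseudocount of 5, fell by 7.89 on the log2 scale, with a standard error of 0.49 (adjusted p = 0.00245), from 704 ± 145 to 1.96 ± 0.381 RPKM (SD, n = 2). The low values rested on more than a few reads. Reads are not independent molecules, however, and their number does not show which region they came from. Phvul.006G125400 had 1082 and 892 recovered reads in the embryo proper libraries, and Phvul.004G006200 had 56 and 55 in the suspensor libraries. With the shared signal subtracted, the log2 fold changes were larger, at 10.28 for Phvul.006G125400 and 10.24 for Phvul.001G029200. They were -8.99 for Phvul.004G006200 and -9.44 for Phvul.009G118900. The amount subtracted was set by the lowest shares, near which these genes lay, so it took nearly all of their lower values. These sizes are therefore not separate estimates. They show only that the size of the differences depended on how the low values were treated. Without either embryo proper library the 4 genes kept their direction but not their call, with limma adjusted p from 0.0591 to 0.0671.

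The lower values of these genes lay near the lowest shares seen, as their choice by largest fold change implies. Phvul.006G125400 and Phvul.001G029200 stood in the embryo proper at 0.948% and 0.890% of their suspensor value, and Phvul.004G006200 and Phvul.009G118900 stood in the suspensor at 0.223% and 0.278% of their embryo proper value. Among the 270 genes with a mean of at least 300 RPKM in the suspensor, the median share in the embryo proper was 78.3%, the lowest was 0.858%, and 15 genes lay between 0.8% and 1.2%. Among the 370 genes with a mean of at least 300 RPKM in the embryo proper, the median share in the suspensor was 37.9%, the lowest was 0.223%, and 7 genes lay between 0.2% and 0.5%.

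**Figure D3:**
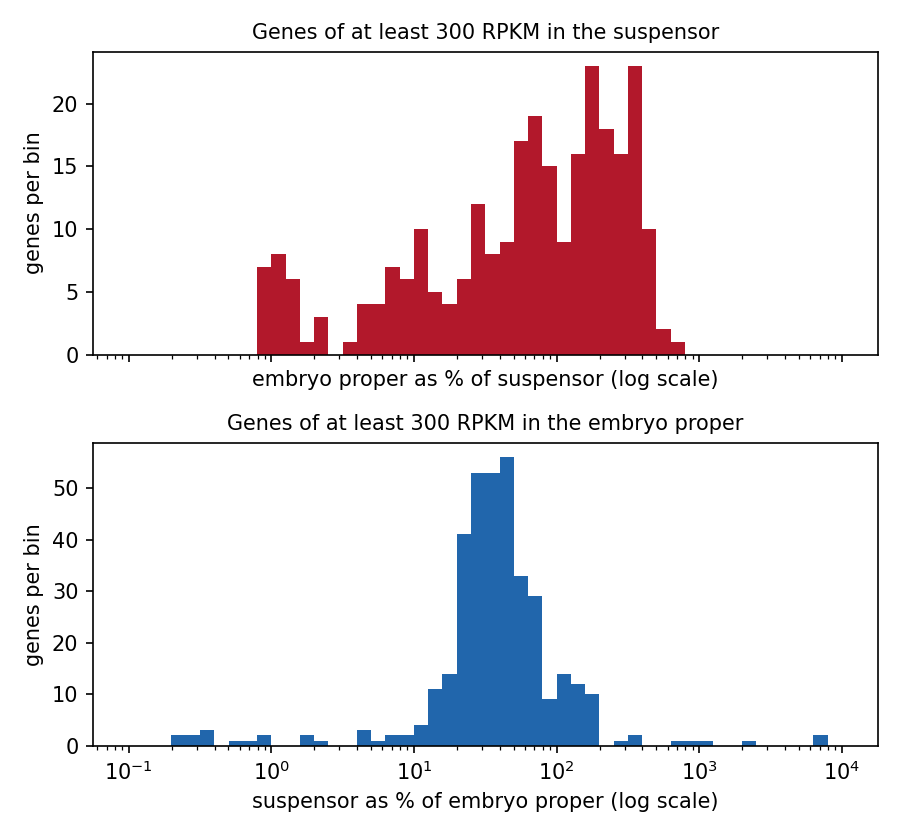
Number of genes (vertical axis) by the mean RPKM of 1 region as a percent of the other (horizontal axis, log scale), for the 270 genes of at least 300 RPKM in the suspensor (top) and the 370 genes of at least 300 RPKM in the embryo proper (bottom). In the top panel the values end at 0.858% with 15 genes between 0.8% and 1.2%, and in the bottom panel they reach down to 0.223%.

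The excess of lower over higher calls depended on how the libraries were scaled. The median log2 fold change of all tested genes was -0.45 with the values as deposited, in which the lower calls made up 69.2% of all calls. With a median ratio rescaling, that median was -0.19 and the calls were 296 higher and 344 lower, or 53.8% lower. With quantile normalization, it was -0.02 and the calls were 363 higher and 336 lower, or 48.1% lower. Both bring the fold changes closer to a median of 0, which by itself evens the calls. Rescaling every library to the same sum went the other way, to a median of -0.63 with 298 higher and 903 lower calls, or 75.2% lower, and voom on the recovered reads gave 74.6% lower. All 344 lower calls of the median ratio rescaling were among the 638, and no call changed direction under any of these. The smallest called log2 fold change was 1.19 in size and the medians moved by less, so a change of direction was unlikely.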

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

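None of the called genes changed direction under any alternative. That outcome was largely built in, since several alternatives keep the same fold changes and the libraries of the regions did not overlap in any called gene. The counts of higher and lower genes (284 and 638) stayed within 1.5 times under a mean of at least 5 RPKM, rescaling every library to the same sum (298 and 903) and robust estimation. They did so too with the added depth without the 10 highest genes of any library (361 and 451). The counts also stayed in that range under both added subtractions of shared signal (312 and 629 at the 1st percentile, 234 and 588 at the 5th). They were 526 and 1337 with a pseudocount of 0.1, 182 and 280 with a pseudocount of 5, and 11 and 10 with no filter, where 19883 genes were tested. At an adjusted p under 0.01 they were 40 and 23, and with a minimum fold change of 2 they were 79 and 73. The lower calls numbered 344 with the median ratio rescaling, 336 with quantile normalization and 423 without a trend. Voom on the recovered reads, added after the data were examined, gave 449 and 1319, with 247 of the 284 and 612 of the 638 among them. A paired fit with the replicate number as a block (replicate block) gave 658 and 1524, although the numbers are not known to pair the samples. Leaving out single libraries gave 0 to 21 higher and 0 to 27 lower genes, fitted with 1 residual degree of freedom fewer and the lone sample taken to vary like the other region. As part of the called set, the 4 named genes also kept their direction in all alternatives, but the sizes varied. The log2 fold changes ranged from 6.33 to 10.72 for Phvul.006G125400 and 6.20 to 10.24 for Phvul.001G029200. They ranged from -8.99 to -6.39 for Phvul.004G006200 and -9.45 to -6.66 for Phvul.009G118900. The largest sizes came under the subtractions, which took nearly all of the lower values of these genes. The 4 named genes lost the call without either embryo proper library, and Phvul.001G029200 also with no filter (limma adjusted p = 0.0519). Genes found only in the embryo proper numbered 426 with limits of 5 and 0.5 RPKM and 957 to 1197 with a library left out, and 787 and 1161 after the subtractions at the 1st and 5th percentile. Those found only in the suspensor numbered 195 to 416 with a library left out and 224 and 269 after the subtractions. Over the tested genes alone, r between replicates was 0.818 in the embryo proper and 0.774 in the suspensor. The 100 most abundant genes held 34.7% and 54.4% of the summed RPKM in the embryo proper and the suspensor. Beyond the changes built into fewer samples or more genes tested, the cause was not tested. The alternatives for gene lists were not run, since no ID was paired with a name here. At the median length 3 reads came to at most 0.0561 RPKM, which limits the counting error only.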

Other observations

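The tests of the shared floor, of the subtraction and of the depth without the highest genes were chosen after the result was seen. Those of the median ratio rescaling and of ID order were chosen before theirs, the latter once 3 successive IDs had been noticed among the highest suspensor genes. The floor test was first made with SDs. Median absolute deviations and another comparator for low transcription were tried after its results were seen, and the verdicts below ask for agreement of both measures. The comparator genes were later matched in level and the bound on the ratio lowered from 1 to 0.707, and the verdicts stayed the same. The upper limit on the share that selects genes for it was also lowered slightly in between, which changed no verdict.

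Some genes called in the same direction carried successive ID numbers. Among 7653 pairs of tested genes with successive numbers, 16 pairs were both higher in the suspensor, against a mean of 3.61 and a highest of 12 in 10000 permutations of the calls within 10 bins of mean RPKM (one-sided permutation p = 0.0001, the smallest they can give). These pairs held 31 of the 284 higher genes, and the longest run was 3 genes. The successive IDs whose notice prompted the test were not left out of these counts. Both members were lower in 30 pairs, against a mean of 17.8 and a highest of 36 in the permutations (one-sided permutation p = 0.0047). The longest run was 4 genes. Pairs called in opposite directions numbered 9, against a mean of 16.0. A candidate explanation is that the pairs are neighbouring gene copies used in the same region. Reads shared between similar copies would also give such pairs, and this stays open because sequences and the treatment of multiply matching reads were not used here.

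The lowest embryo proper shares of abundant suspensor genes lay near 1%. Of 270 genes, 15 stood between 0.8% and 1.2% of their suspensor value and 0 lower, while the median share was 78.3%. In the 14 genes of at least 300 RPKM in the suspensor that lay under 1.2% in embryo proper replicate 2, embryo proper replicate 1 stood at a median of 0.969% of the mean of both suspensor libraries. Its robust scatter around that fraction was 0.147 (log2), against 0.362 around suspensor replicate 1 alone, 0.343 around suspensor replicate 2 alone, and 1.46 between embryo proper replicates in the 50 genes nearest to each in embryo proper RPKM. A single library of separately amplified RNA should scatter by at least 0.707 of the difference between 2 such replicates. The ratio was 0.859 in simulated carry-over, where the suspensor values vary too, and 0.003 in simulated mixing. Both simulations gave all genes the same noise, so they do not test how noisy carried-over RNA is. In the data, the upper 95% bootstrap limit of the scatter ratio was 0.656 from SDs and 0.402 from median absolute deviations. If such RNA is as noisy as other RNA at that level, these limits argue against suspensor cells captured with the embryo proper. Mixing of libraries after amplification, such as reads assigned to the wrong library, is a hypothesis that the test did not decide, since it asked for upper limits under 0.5 by both measures. The ratio was at most 0.432 from SDs and 0.211 from median absolute deviations, above that of the simulated mixing. Low transcription of these genes in the embryo proper would also be separately amplified RNA, at the level of the comparator genes. If these genes are as noisy as others at that level, the same limits of 0.656 and 0.402 argue against it too. The other comparator, tried for it after the first results were seen, did not decide. There the scatter relative to that between suspensor replicates in the same genes had upper limits of 1.72 from SDs and 0.933 from median absolute deviations. Both lie above the 0.707 that would exclude it. In the 18 genes chosen on replicate 1, the robust scatter of replicate 2 was 0.291 around the mean, 0.343 around suspensor replicate 1 alone and 0.848 around suspensor replicate 2 alone, with 1 gene at 10.2%. No label says whether the libraries were sequenced together.

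More genes were lower than higher in the suspensor, and more were found only in the embryo proper. Either could come from scaling, since a few abundant suspensor genes take a large part of the reads, and this stays open. The counts of genes found only in 1 region were not repeated with another scaling. The 23 genes that were among the 10 highest of any library held 25.0% and 34.6% of the depth in suspensor replicates 1 and 2, against 10.8% and 9.24% in embryo proper replicates 1 and 2. With the depth counted without them 55.5% of the calls were lower (361 higher, 451 lower), against 69.2% as deposited. This scales the RPKM of all genes alike, by about 0.361 (log2) more in the suspensor, before the pseudocount is added. The median ratio rescaling, the test planned first, centres the fold changes. Neither therefore decides whether the 23 genes are the cause. Rescaling to an equal sum gave 75.2% lower. To subtract the shared signal, 0.912% and 0.935% of the suspensor mean were taken from embryo proper replicates 1 and 2. From suspensor replicates 1 and 2, 0.239% and 0.360% of the embryo proper mean were taken. These amounts are the 1st percentile of the shares. After this, 66.8% of the calls were lower. Genes found only in the embryo proper numbered 3.51 for each found only in the suspensor, against 6.68 before. Among abundant suspensor genes under 1.2% in the other embryo proper library, the median share was 0.969% in embryo proper replicate 1 and 1.10% in replicate 2. The amounts taken were smaller, so part of that signal remained. The subtraction therefore does not decide whether that signal is the cause of either excess. The 5th percentile was tried first, took 5.70% and 5.26% from suspensor replicates 1 and 2, and left 71.5% of the calls lower. A wider set of genes in use in the embryo proper stays open and was not tested.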
